A study of Mus musculus with 186 samples.

How the data were processed

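Lung (superior lobe) and skin of the same treatment groups were sequenced as stranded total RNA after removal of ribosomal RNA, per the labels. Groups, days and plates were taken from the sample titles and labels, and no library was moved between groups or left out of the main tests. The authors deposited expected counts per gene, which per the submitters' processing notes came from RSEM on GRCm38. The aligner and the versions were not given in the sources used here. The authors also deposited log2 CPM (counts scaled to library size) of expressed protein-coding genes, made with edgeR and corrected for plate per the submitters' processing notes and the table's title.

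The count table held 22095 gene IDs, of which 21852 were paired with a GENCODE M21 name, 243 were not and 97.9% were annotated as protein coding, so that few noncoding transcripts were in the table. The log2 table held 16160 of these IDs. Of the counts 83.7% were whole numbers, and all were rounded to integers. Total counts ran from 4.79 to 43.07 M (mega counts) per library with a median of 19.695 M, and 0 pairs of libraries had identical counts.

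Genes were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 after filterByExpr by group and TMM scaling. All 12 groups of a tissue entered a fit with plate as a term, so that groups shared estimates of spread. Bleomycin was compared with PBS on each day, with vehicle groups on both sides from day 21, and SB525334 with vehicle on days 21 and 28. Contrasts of contrasts tested day 42 minus day 14, an F test covered all 5 days, and another the PBS groups. Skin minus lung used the libraries of both tissues with a plate term per tissue. The labels match no mice between tissues, and libraries were treated as independent. Genes were called at a Benjamini-Hochberg adjusted p below 0.050. Standard errors were taken as the absolute log2 fold change over the square root of F, an approximation. Levels are CPM with TMM scaling.

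Of 51 gene lists, 41 for lung and 43 for skin, those with at least 5 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.010, with camera at an estimated correlation and with fry. Camera p-values were adjusted over the lists of a comparison. Members were also counted as up or down with p-values adjusted over the list alone. Lists named after cell types describe marker transcripts in bulk tissue, not cell numbers. Lists and rules were written without a look at the values. Genes called at day 14 of bleomycin were followed as sets under SB525334, since these comparisons share no libraries.

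Named genes followed a rule. It took the 5 largest rises and falls among genes called in a comparison with a mean log2 CPM of at least 1 and a gene symbol other than a clone or model name. It added 12 genes chosen in advance for fibrosis, injury and proliferation, and up to 4 members with the smallest p of each list described, with members of the opposite direction where a list was split. For differences of effects it took the 5 smallest p per direction, and for F tests the 10 smallest. Not every gene the rule allowed is printed.

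The procedure was tested on simulated data with 200 changed genes in the day 7 comparison. In lung edgeR recovered 92 of 100 genes changed 2-fold and 76 of 100 changed 1.5-fold with 5 false calls, and in skin 91 and 73 with 8. Signs of called genes were checked in each plate alone. Random regroupings of the libraries were counted with limma-trend on log2 CPM with a prior count of 2.

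Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma voom with quality weights, limma-trend on the deposited log2 table, no plate term, 4 plate sections as a term, the replicate number as a block, and fits of the 2 groups compared alone. For sets of genes they were the estimated correlation, fry, a signature limited to at least 2-fold changes and one from day 7. Further alternatives, chosen after seeing the data, left out lung libraries of unusual composition or added hair and muscle scores as terms in skin.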

Results

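Bulk RNA of lung and back skin was sequenced in a mouse model of scleroderma, a fibrotic disease. Female C57BL/6 mice received subcutaneous bleomycin, a DNA-cleaving antibiotic that injures tissue and induces fibrosis, at 10 mg/kg/day, or phosphate-buffered saline (PBS), 5 times per week for 2 weeks. From day 12 the mice kept beyond day 14 were given oral vehicle or, in 2 bleomycin groups, SB525334 at 30 mpk BID, an inhibitor of ALK5, the kinase of the TGF-beta type I receptor. Tissue was taken on days 7, 14, 21, 28 and 42, which gave 93 libraries per tissue, in 24 groups of 7 to 9. Total expected counts per library ranged from 4.79 to 38.34 M in lung and from 14.68 to 43.07 M in skin.

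The comparisons of bleomycin with PBS asked what the injury changed on each day in each tissue, and those of SB525334 with vehicle what ALK5 inhibition changed in bleomycin-treated mice on days 21 and 28. Further tests asked whether the bleomycin effect differed between days and between tissues, and how PBS tissue changed between days. In the text a gene is followed by its log2 fold change ± standard error (SE). Genes said to rise or fall passed an adjusted p of 0.05 in edgeR, and other genes are given as values only. Other list members did not pass. Counts within the list rest on p-values adjusted over that list alone. Lists give the adjusted p of camera at a preset and, where said to be estimated, at an estimated correlation. Ranges of the share of increases are over all alternatives that called genes. Doubted lung libraries, 15 in all, are defined in the closing section. The libraries were treated as independent. P-values rest on a spread between samples shared by all groups of a fit, not of the compared ones alone. Plate values count the called genes with the same sign in both sequencing plates. The genes were called from these same libraries, so a high share is no replication.

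Anchor genes chosen in advance included Col1a1 (collagen I), Col3a1 (collagen III), Fn1 (fibronectin), Postn (periostin), Acta2 (smooth muscle actin), Ccn2 (connective tissue growth factor), Timp1, Cdkn1a (p21), Spp1 (osteopontin), Ccl2 and Mki67, a proliferation marker.

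**Figure D1:**
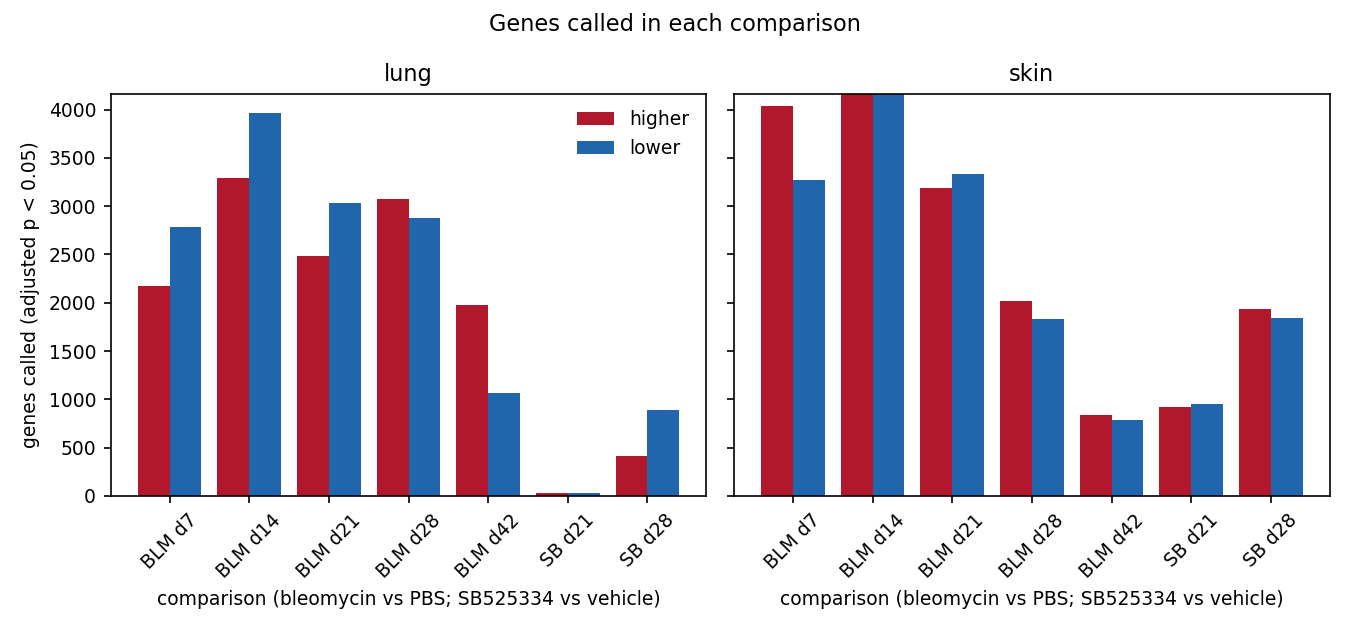
Number of genes called per comparison (y axis, genes at adjusted p below 0.05), with increases in red and decreases in blue, for lung and skin. The largest count was that of skin at day 14, 9428, and the smallest that of SB525334 in lung at day 21, 59.

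In the lung at day 7 (7 bleomycin and 8 PBS), the largest increases were of Chil4 (6.40 ± 1.02) and Clca1 (5.33 ± 0.71), which mark allergic-type airway inflammation, Gdf15 (3.24 ± 0.25), a stress cytokine, Retnla (3.15 ± 0.42), a marker of alternatively activated macrophages, and Timp1 (3.08 ± 0.52), a metalloproteinase inhibitor, each above the PBS mean in 7 of 7 lungs (adjusted p = 6.14e-18 for Gdf15). The p53 arm of the DNA damage response rose, led by Ccng1 (1.77 ± 0.11), Eda2r (2.62 ± 0.19) and Cdkn1a (1.99 ± 0.18). Of 32 p53 targets 21 were up and 3 down, 22 up and 3 down within the list, at camera adjusted p = 1.12e-23 and adjusted p = 5.56e-07 when estimated. All cell cycle genes rose, among them Ccne2 (1.90 ± 0.23), Mcm2 (1.14 ± 0.14) and Mki67 (1.78 ± 0.31). Of 35 cell cycle genes 35 were up, the same within the list, at camera adjusted p = 3.6e-37 and adjusted p = 0.0728 when estimated. Macrophage genes rose, with Msr1 (2.02 ± 0.38) and Cd68 (1.03 ± 0.20). Of 25 macrophage genes 16 were up and 1 down, 21 up and 1 down within the list, at camera adjusted p = 3.92e-07 and adjusted p = 0.25 when estimated. Interferon-induced genes rose, with Ifit1 (0.99 ± 0.14) and Oas1a (0.98 ± 0.19). Of 27 interferon-induced genes 19 were up, the same within the list, at camera adjusted p = 1.35e-08 and adjusted p = 0.25 when estimated. The monocyte attractant Ccl2 (1.81 ± 0.45) and Spp1 (1.28 ± 0.31), a macrophage product linked with fibrosis, also rose. Matrix genes rose, with Tnc (1.68 ± 0.35), Vcan (1.55 ± 0.25), Fn1 (0.77 ± 0.29) and Col3a1 (0.70 ± 0.25), while values were Col1a1 (0.20 ± 0.34), Postn (0.26 ± 0.13) and Acta2 (-0.13 ± 0.12). Of 30 matrix genes 10 were up, the same within the list, at camera adjusted p = 0.00438 and adjusted p = 0.782 when estimated. The endothelial gene Esm1 (-1.14 ± 0.25) fell. The largest decreases, such as Krt31 (-8.88 ± 1.69) and Prr9 (-8.55 ± 1.61), were of hair genes counted in 2 PBS libraries that also held epidermal transcripts (without such libraries Krt31 did not pass the count filter). In all 4956 of 15647 genes were called, 2168 up and 2788 down, 459 and 336 of them at least 2-fold, and 98.3% had the same sign in both plates. Bleomycin R2 and R6 held 24.36% and 24.96% of their counts in 10 genes, against 5.91% to 6.84% in the other 5 lungs, and more genes were detected in them, 18981 and 19768. The predicted gene Gm10800, chosen after its values were seen, held 15.39% and 15.4% of counts. Without these libraries and a similar one of PBS day 14, a test chosen after seeing the data, 3806 genes were called and Fn1 was 0.80 (adjusted p = 0.0577). Fold changes fell with exon length (Spearman rho = -0.252, and -0.204 without libraries high in ribosomal protein genes, here called high-RP). Of the calls 43.7% were increases (42.7% with deposited log2 values to 52.7% without doubted libraries).

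At day 14 (8 and 8) macrophage, matrix and DNA damage genes rose. The largest increases were of Mmp12 (4.36 ± 0.46), a macrophage elastase, Retnla (4.07 ± 0.44), Gdf15 (3.81 ± 0.25), Col28a1 (3.59 ± 0.33), a minor collagen, and the p53 target Psrc1 (3.52 ± 0.30), each above the PBS mean in 8 of 8 lungs (adjusted p = 1.44e-12 for Mmp12). Genes of SPP1-expressing, lipid-associated macrophages, a population of fibrotic lung, rose, with Spp1 (3.33 ± 0.33), Trem2 (3.50 ± 0.35) and Ctsd (1.78 ± 0.14). Of 23 lipid-associated macrophage genes 15 were up and 1 down, 15 up and 2 down within the list, at camera adjusted p = 7.42e-09 and adjusted p = 0.0335 when estimated. So did those of transitional alveolar epithelium, a stressed state of alveolar progenitors, with Cdkn1a (2.60 ± 0.18), Tnip3 (1.95 ± 0.19) and Krt18 (1.06 ± 0.12). Of 20 transitional epithelium genes 14 were up and 1 down, the same within the list, at camera adjusted p = 2.99e-11 and adjusted p = 0.0221 when estimated. Targets of p53 rose, with Ccng1 (2.21 ± 0.11) and Mdm2 (0.88 ± 0.05). Among p53 targets 24 of 32 were up and 2 down, the same within the list, at camera adjusted p = 8.58e-25 and adjusted p = 2.66e-07 when estimated. Inflammatory genes rose, with Lif (2.72 ± 0.23), Lcn2 (2.52 ± 0.22) and Ccl2 (2.84 ± 0.44). Of 23 inflammatory genes 13 were up and 1 down, 13 up and 2 down within the list, at camera adjusted p = 7.21e-07 and adjusted p = 0.0412 when estimated. Matrix genes rose, with Fn1 (1.99 ± 0.29), Tnc (3.03 ± 0.36), Col3a1 (1.06 ± 0.25), Col1a1 (0.94 ± 0.33) and Timp1 (2.17 ± 0.47), next to Ccn2 (0.78 ± 0.14), and again not Postn (0.14 ± 0.12) or Acta2 (0.09 ± 0.11). Among matrix genes 20 of 30 were up and 1 down, 21 up and 1 down within the list, at camera adjusted p = 7.21e-07 and adjusted p = 0.391 when estimated. Endothelial genes fell, with Ednrb (-1.18 ± 0.17) and Cdh5 (-0.57 ± 0.10), and so did Igfbp3 (-3.23 ± 0.24), a binding protein of growth factors. Of 23 endothelial genes 21 were down, the same within the list, at camera adjusted p = 4.71e-08 and adjusted p = 0.195 when estimated. Hair genes led the decreases, for example Krtap11-1 (-7.41 ± 1.44) and Krtap16-3 (-7.26 ± 1.44), and came from 1 PBS library (Krtap11-1 0.30 without it). Of 15647 genes 7256 were called, 3288 up and 3968 down (619 and 487 at least 2-fold). In both plates 96.6% had the same sign, though plate 1 held only 1 lung per group. The Spearman correlation of fold change with exon length was -0.233, and -0.164 without high-RP libraries. Of the calls 45.3% were increases (44.4% with RLE to 50.7% without doubted libraries).

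By day 21 (7 and 8), 1 week after the last injection, the largest increases were of Mmp12 (4.82 ± 0.47), Spp1 (3.89 ± 0.34) and Trem2 (3.82 ± 0.37), all of macrophages, and of the acute-phase gene Saa3 (3.59 ± 0.88), each above the PBS mean in 7 of 7 lungs (adjusted p = 8.53e-16 for Spp1). Genes of lipid-associated macrophages rose. Among lipid-associated macrophage genes 15 of 23 were up and 1 down, the same within the list, at camera adjusted p = 2.64e-15 and adjusted p = 0.00146 when estimated. Those of macrophages at large rose, with Ctss (2.24 ± 0.20) and Cd68 (1.77 ± 0.20). Among macrophage genes 21 of 25 were up, the same within the list, at camera adjusted p = 7.82e-19 and adjusted p = 0.0152 when estimated. Transitional epithelium genes rose, with Cdkn1a (1.95 ± 0.18) and Tnip3 (2.07 ± 0.19). Among transitional epithelium genes 15 of 20 were up, 17 up within the list, at camera adjusted p = 1.58e-14 and adjusted p = 0.00316 when estimated. So did p53 targets, with Psrc1 (3.61 ± 0.31) and Eda2r (2.69 ± 0.19). The count of p53 targets was 22 up and 3 down of 32, 23 up and 3 down within the list, at camera adjusted p = 9.06e-21 and adjusted p = 2.71e-06 when estimated. Matrix genes rose, with Tnc (3.02 ± 0.37), Eln (2.02 ± 0.29), Fn1 (1.93 ± 0.30), Col1a1 (1.17 ± 0.34), Col3a1 (1.09 ± 0.25) and Postn (0.32 ± 0.13), next to the proteases Ctsk (2.20 ± 0.21) and Mmp2 (1.68 ± 0.17), Timp1 (2.68 ± 0.50) and Ccn2 (1.34 ± 0.15). The count of matrix genes was 22 up of 30, the same within the list, at camera adjusted p = 8.8e-11 and adjusted p = 0.199 when estimated. Among lymphocyte genes, those of B cells fell, with Bank1 (-1.40 ± 0.29) and Pax5 (-1.33 ± 0.30). Of 15 B cell genes 14 were down, 15 down within the list, at camera adjusted p = 9.59e-06 and adjusted p = 0.328 when estimated. Those of T and NK cells fell, with Cd8a (-1.22 ± 0.23) but not the regulatory T cell gene Ctla4 (1.55 ± 0.21), which rose. Of 22 T and NK cell genes 16 were down and 2 up, 17 down and 2 up within the list, at camera adjusted p = 8.86e-04 and adjusted p = 0.353 when estimated. Beside these falls, red cell transcripts summed to 2480 to 4890 CPM after bleomycin, except 12200 in R3, against 4230 to 14200 in PBS. Other large decreases were those of Rag1 (-3.85 ± 1.04), a recombinase of immature lymphocytes, Fabp1 (-3.29 ± 0.90), Cst8 (-2.61 ± 0.41), Bex2 (-2.60 ± 0.33) and Igfbp3 (-2.54 ± 0.24). Called were 5521 genes, 2487 up and 3034 down (647 and 184 at least 2-fold), with 99.9% of the same sign in both plates, against 8695 genes with only the 2 groups and 9231 with limma voom. The Spearman correlation of fold change with exon length was -0.17, and -0.139 without high-RP libraries. Of the calls 45% were increases (44.1% with limma voom to 53.4% with no filter).

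At day 28 (7 and 7) Spp1 (3.35 ± 0.35), Trem2 (2.91 ± 0.38) and Mmp12 (4.64 ± 0.51) rose, Spp1 in 7 of 7 lungs (adjusted p = 2.14e-11), and so did p53 targets, with Eda2r (2.18 ± 0.20), Phlda3 (1.32 ± 0.14) and Cdkn1a (1.48 ± 0.18). Of 32 p53 targets 19 were up and 3 down, 21 up and 5 down within the list, at camera adjusted p = 1.49e-10 and adjusted p = 0.00308 when estimated. Lipid-associated macrophage genes rose. The count of lipid-associated macrophage genes was 13 up and 2 down of 23, the same within the list, at camera adjusted p = 4.33e-07 and adjusted p = 0.137 when estimated. Matrix genes rose, among them Mfap5 (0.94 ± 0.16), Bgn (0.60 ± 0.14) and Fn1 (1.38 ± 0.31), with Col1a1 (1.34 ± 0.36) and Ccn2 (0.68 ± 0.15) up and Col3a1 (0.35 ± 0.26), Postn (0.06 ± 0.13) and Acta2 (-0.18 ± 0.12) not called. Of 30 matrix genes 12 were up and 1 down, the same within the list, at camera adjusted p = 1.33e-04 and adjusted p = 0.577 when estimated. TGF-beta responsive genes rose, with Pmepa1 (0.84 ± 0.14), Itgb6 (0.69 ± 0.13) and Ltbp2 (1.37 ± 0.28). Of 28 TGF-beta responsive genes 14 were up and 2 down, the same within the list, at camera adjusted p = 0.00693 and adjusted p = 0.473 when estimated. Endothelial genes fell, with Cldn5 (-0.71 ± 0.12) and Tek (-0.83 ± 0.15). Among endothelial genes 17 of 23 were down, 19 down within the list, at camera adjusted p = 3.65e-09 and adjusted p = 0.228 when estimated. The other main decreases were Ngp (-3.04 ± 0.83), Apol11b (-2.65 ± 0.56) and Col6a5 (-2.01 ± 0.49). The largest increases, Krt4 (11.30 ± 1.33), Myh8 (11.00 ± 1.49) and Tgm3 (6.85 ± 1.21), were of squamous epithelium and muscle and rested on 1 bleomycin library, Tgm3 above the PBS mean in only 1 of 7 lungs and -1.39 without it, Krt4 1.71. Interferon genes rose, but without the doubted libraries 3 rose (camera adjusted p = 0.533), and the cell cycle count went from 13 to 2 of 35. Among interferon-induced genes 13 of 27 were up and 1 down, 14 up and 1 down within the list, at camera adjusted p = 0.00693 and adjusted p = 0.577 when estimated. Called were 5948 genes, 3075 up and 2873 down (612 and 140 at least 2-fold). Fitted alone, the 2 groups gave only 112 genes, and 3693 were called without high-RP libraries and 3471 without all doubted ones. Plate 2 held 2 lungs per group, and 62.9% of the called genes had the same sign in both plates. Fold changes fell with exon length (rho = -0.247), but not without high-RP libraries (rho = 0.0343). Of the calls 51.7% were increases (48.1% with deposited log2 values to 74.1% with the 2 groups alone).

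At day 42 (8 and 8), 4 weeks after the last injection, macrophage genes rose, with Ms4a7 (2.36 ± 0.33) and Ctss (1.38 ± 0.19), and so did Trem2 (2.87 ± 0.36), Spp1 (2.39 ± 0.31) and Mmp12 (3.30 ± 0.44), Spp1 in 8 of 8 lungs (adjusted p = 1.04e-08). The count of macrophage genes was 15 up and 2 down of 25, 17 up and 2 down within the list, at camera adjusted p = 2.16e-10 and adjusted p = 0.106 when estimated. So did p53 targets, with Psrc1 (2.63 ± 0.30), Eda2r (2.33 ± 0.18), Gdf15 (2.20 ± 0.24) and Cdkn1a (0.97 ± 0.17). Among p53 targets 16 of 32 were up and 2 down, 18 up and 3 down within the list, at camera adjusted p = 1.6e-12 and adjusted p = 5.71e-04 when estimated. Matrix genes rose, with Tnc (2.23 ± 0.35), Fn1 (1.46 ± 0.29) and Sparc (0.56 ± 0.13), while values of Col1a1 (0.69 ± 0.33), Col3a1 (0.56 ± 0.24), Postn (0.15 ± 0.12) and Timp1 (1.21 ± 0.50) were not called. Among matrix genes 13 of 30 were up, 17 up within the list, at camera adjusted p = 2.96e-06 and adjusted p = 0.349 when estimated. Basement membrane genes rose, with Lama1 (2.52 ± 0.30) and Col4a1 (0.79 ± 0.16). Of 22 basement membrane genes 13 were up and 1 down, 15 up and 1 down within the list, at camera adjusted p = 1.76e-06 and adjusted p = 0.319 when estimated. Antigen presentation genes rose, with H2-Ab1 (0.78 ± 0.13) and Cd74 (0.64 ± 0.11). Of 20 antigen presentation genes 7 were up, 9 up within the list, at camera adjusted p = 9.9e-05 and adjusted p = 0.319 when estimated. B cell genes rose, though they had camera adjusted p = 0.436 without the doubted libraries. Among B cell genes 4 of 15 were up, 9 up within the list, at camera adjusted p = 0.0112 and adjusted p = 0.533 when estimated. Fibroblast markers fell, with Inmt (-1.28 ± 0.24) and Pdgfra (-0.80 ± 0.11), although Cd34 (0.42 ± 0.09) rose. Of 20 fibroblast markers 7 were down and 1 up, the same within the list, at camera adjusted p = 1.94e-04 and adjusted p = 0.0367 when estimated. Cardiac muscle genes, whose source in the lobe was not tested, fell, with Tnni3 (-0.97 ± 0.19). Of 14 cardiac muscle genes 12 were down, 13 down within the list, at camera adjusted p = 8.2e-11 and adjusted p = 0.0806 when estimated. The largest single decreases were of Bex2 (-2.50 ± 0.32), Krt79 (-2.49 ± 0.46) and Cst8 (-2.23 ± 0.39). The largest increases were of liver genes from 1 doubted library, such as Mup3 (168 ± 476 CPM against 0.017 ± 0.0241, above the PBS mean in 3 of 8 lungs) and Bhmt (194 ± 548 CPM against 0 ± 0). Called were 3037 genes, 1974 up and 1063 down (611 and 111 at least 2-fold), with 92.8% of the same sign in both plates, against 5531 genes with limma voom. Of the calls 65% were increases (50.2% with deposited log2 values to 71.5% with no filter).

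SB525334 in day 21 lung (9 against 7 on vehicle) was tested. Haemoglobin and erythroid genes rose, with Hba-a2 (1.95 ± 0.48) and Alas2 (1.72 ± 0.38), the latter above the vehicle mean in 9 of 9 lungs (adjusted p = 0.00975). Of 11 red cell genes 7 were up, 11 up within the list, at camera adjusted p = 9.84e-18 and adjusted p = 0.0512 when estimated. Red cell transcripts summed to 51200 CPM in R6 and 23400 in R9 of the treated lungs, with 4580 to 11600 in the other 7, and to 12200 in vehicle R3, with 2480 to 4890 in the other 6. Matrix genes shifted down as a list only at the preset correlation, with Mfap5 (-0.70 ± 0.14), Bgn (-0.57 ± 0.13) and Fbln1 (-0.48 ± 0.12), and among the lowest single genes were C1qtnf3 (-1.50 ± 0.30), Itgbl1 (-1.09 ± 0.19), Spon2 (-1.08 ± 0.22) and Cthrc1 (-0.97 ± 0.18), all of activated fibroblasts, and Cd209a (-0.98 ± 0.20). The count of matrix genes was 3 down of 30, 16 down within the list, at camera adjusted p = 2.89e-21 and adjusted p = 0.0821 when estimated. Clock genes shifted, with Dbp (1.52 ± 0.25), Hlf (1.20 ± 0.21) and Per3 (0.90 ± 0.15) up and Arntl (-0.82 ± 0.14) down. Of 18 clock genes 5 were up and 1 down, 7 up and 3 down within the list, at camera adjusted p = 2.16e-09 and adjusted p = 0.00701 when estimated. Of the genes chosen in advance, values not called were Col1a1 (-0.78 ± 0.33), Col3a1 (-0.69 ± 0.24), Fn1 (-0.09 ± 0.28), Postn (-0.33 ± 0.12), Spp1 (-0.50 ± 0.30) and Cdkn1a (-0.34 ± 0.17). Basement membrane genes had a negative median. Among basement membrane genes 0 of 22 were down, 5 down within the list, at camera adjusted p = 9.7e-13 and adjusted p = 0.145 when estimated. Called were 59 genes, 25 up and 34 down, against 1136 at nominal p below 0.05, and 100% had the same sign in both plates. The count was 890 with only the 2 groups, 1316 with limma voom, 127 with DESeq2, 150 without libraries with other tissues, 140 without high-RP ones and 337 without all doubted ones. Of the calls 42.4% were increases (25% with deposited log2 values to 59.7% with limma voom).

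In the day 28 lung (8 against 7) SB525334 lowered matrix genes, with Fbn2 (-2.08 ± 0.32), Col8a1 (-1.22 ± 0.17), Bgn (-0.84 ± 0.13), Col1a1 (-1.02 ± 0.34), Col3a1 (-0.99 ± 0.25) and Postn (-0.54 ± 0.13). Of 30 matrix genes 22 were down, 26 down within the list, at camera adjusted p = 5.18e-19 and adjusted p = 0.117 when estimated. Basement membrane genes fell, with Lama2 (-0.60 ± 0.10). The count of basement membrane genes was 16 down of 22, 20 down within the list, at camera adjusted p = 2.58e-16 and adjusted p = 0.117 when estimated. Without the doubted libraries, which included 6 of the 8 treated and 4 of the 7 vehicle lungs, 2 matrix genes fell (camera adjusted p = 0.00343) and 1 of the basement membrane, and Postn was 0.06 and Col1a1 -2.11. Lymphatic endothelial genes fell, with Prox1 (-0.77 ± 0.19) and Reln (-0.72 ± 0.11), and so did Spp1 (-1.12 ± 0.31), while Fn1 (-0.49 ± 0.29), Ccn2 (-0.38 ± 0.15) and Cdkn1a (-0.36 ± 0.17) were not called. Of 9 lymphatic endothelial genes 6 were down, the same within the list, at camera adjusted p = 8.84e-07 and adjusted p = 0.00474 when estimated. T and NK cell genes rose, with Gzmb (0.87 ± 0.21) and Nkg7 (0.83 ± 0.23). Among T and NK cell genes 6 of 22 were up, 12 up within the list, at camera adjusted p = 3.17e-07 and adjusted p = 0.312 when estimated. Neutrophil genes rose, with Stfa2l1 (2.70 ± 0.61), S100a8 (1.78 ± 0.51) and S100a9 (1.71 ± 0.46). Of 15 neutrophil genes 7 were up, 7 up and 1 down within the list, at camera adjusted p = 5.39e-05 and adjusted p = 0.317 when estimated. Beside all these changes, fold changes fell with exon length (Spearman rho = -0.401, and -0.0401 without high-RP libraries). Other leading increases were Rpl10-ps3 (2.38 ± 0.67), Ifitm6 (1.81 ± 0.37) and Retnlg (1.49 ± 0.40), with Rpl10-ps3 -0.26 without the doubted libraries. The largest decreases, Krt4 (-10.35 ± 1.20), Myh8 (-10.28 ± 1.37) and Acta1 (-6.81 ± 1.07), were of squamous epithelium and muscle, found in 1 vehicle library (Krt4 -0.87 without the doubted libraries). Called were 1301 genes, 412 up and 889 down, with 76.2% of the same sign in both plates, and none when only the 2 groups were fitted in edgeR, where 1388 had nominal p below 0.05, DESeq2 calling 1543 and limma voom 43 in the model of all groups. The count was 683 without libraries with other tissues, 66 without high-RP ones and 142 without all doubted ones. Of the calls 31.7% were increases (14% with limma voom to 44.4% with deposited log2 values).

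In the skin at day 7 (7 and 8) epidermal wound, interferon and DNA damage genes rose while fibroblast genes fell. The largest increases were of Krt6b (7.63 ± 1.43), a keratin of wounded epidermis, Tmprss11b (6.90 ± 0.76), a squamous protease, S100a8 (6.05 ± 0.99), a neutrophil alarmin, BC100530 (5.88 ± 0.88), a stefin-type inhibitor, and Akr1d1 (5.83 ± 0.85), each above the PBS mean in 7 of 7 samples (adjusted p = 1.17e-05 for Krt6b). Every interferon-induced gene rose, with Isg15 (2.72 ± 0.35). The count of interferon-induced genes was 27 up of 27, the same within the list, at camera adjusted p = 5.97e-21 and adjusted p = 0.218 when estimated. Targets of p53 rose, with Pmaip1 (1.55 ± 0.14) and Cdkn1a (0.95 ± 0.09). The count of p53 targets was 25 up and 1 down of 32, 25 up and 2 down within the list, at camera adjusted p = 4.37e-14 and adjusted p = 1.3e-05 when estimated. T and NK cell genes rose, with Gzmb (2.82 ± 0.37) and Cd8a (2.19 ± 0.31). The count of T and NK cell genes was 19 up of 22, the same within the list, at camera adjusted p = 2.17e-12 and adjusted p = 0.205 when estimated. Wound keratinocyte genes rose, with Krt16 (5.13 ± 0.79). Of 20 wound keratinocyte genes 16 were up, the same within the list, at camera adjusted p = 1.02e-05 and adjusted p = 0.476 when estimated. Fibroblast markers fell, with Clec3b (-2.27 ± 0.32) and Pdgfra (-1.61 ± 0.15). Among fibroblast markers 14 of 20 were down and 1 up, 15 down and 1 up within the list, at camera adjusted p = 4.75e-09 and adjusted p = 0.205 when estimated. Matrix genes were split towards decreases, with Mfap5 (-1.27 ± 0.25), Dcn (-0.99 ± 0.19), Fn1 (-1.15 ± 0.24) and Col3a1 (-0.67 ± 0.24) down, Tnc (1.65 ± 0.49) and Col8a1 (1.06 ± 0.36) up, and Col1a1 (-0.61 ± 0.28), Postn (0.27 ± 0.24) and Acta2 (-0.23 ± 0.12) not called. Among matrix genes 12 of 30 were down and 3 up, the same within the list, at camera adjusted p = 0.00455 and adjusted p = 0.647 when estimated. Timp1 (1.59 ± 0.33), Spp1 (2.03 ± 0.55), Ccl2 (1.45 ± 0.34) and Mki67 (0.87 ± 0.26) rose. The largest decreases were of the muscle myosins Myh7 (-4.87 ± 1.53) and Myh2 (-3.56 ± 0.94), Hamp2 (-4.11 ± 0.71), Plac9a (-4.04 ± 0.79) and the macrophage receptor Marco (-3.35 ± 0.72). Called were 7309 of 15825 genes, 4036 up and 3273 down (886 and 563 at least 2-fold), with 99.6% of the same sign in both plates. Skeletal muscle transcripts had a median sum of 8350 CPM against 23700 in PBS. Of the calls 55.2% were increases (48.3% with deposited log2 values to 55.6% with replicate block).

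At day 14 (8 and 8) skin had the most called genes of any comparison, 9428, with 4983 up and 4445 down (1197 and 1208 at least 2-fold). Krt6b (8.60 ± 1.47), Tmprss11b (8.38 ± 0.75), BC100530 (7.65 ± 0.95), Akr1d1 (7.61 ± 0.88) and the neutrophil attractant Cxcl2 (7.85 ± 0.98) rose most, each in 8 of 8 samples (adjusted p = 1.24e-10 for Cxcl2). Wound keratinocyte genes rose, with Sprr1b (6.51 ± 0.81) and Krt16 (6.54 ± 0.83). Among wound keratinocyte genes 18 of 20 were up, the same within the list, at camera adjusted p = 2.24e-06 and adjusted p = 0.329 when estimated. Neutrophil genes rose, with S100a9 (7.20 ± 0.94) and Cxcr2 (3.97 ± 0.50). Among neutrophil genes 12 of 13 were up and 1 down, the same within the list, at camera adjusted p = 0.00215 and adjusted p = 0.47 when estimated. The cytokine Il1b (4.72 ± 0.63) rose, as did Spp1 (4.41 ± 0.58), Timp1 (2.68 ± 0.34) and Ccl2 (1.84 ± 0.34). So did interferon-induced genes, with Ifi44 (2.64 ± 0.33). Of 27 interferon-induced genes 26 were up, the same within the list, at camera adjusted p = 1.6e-13 and adjusted p = 0.348 when estimated. Targets of p53 rose, with Pmaip1 (2.11 ± 0.14) and Cdkn1a (0.95 ± 0.09). Of 32 p53 targets 27 were up and 1 down, the same within the list, at camera adjusted p = 2.43e-11 and adjusted p = 7.25e-05 when estimated. All but 1 of the fibroblast markers fell, with Clec3b (-4.39 ± 0.35), Cd34 (-2.30 ± 0.20) and Pdgfra (-2.06 ± 0.15). The count of fibroblast markers was 19 down and 1 up of 20, the same within the list, at camera adjusted p = 1.6e-13 and adjusted p = 0.070 when estimated. Matrix genes mostly fell, with Dcn (-2.10 ± 0.19), Eln (-2.04 ± 0.26), Fn1 (-1.40 ± 0.23), Col3a1 (-1.15 ± 0.24) and Col1a1 (-1.14 ± 0.27) down and Tnc (3.15 ± 0.51), Col8a1 (1.94 ± 0.35), Thbs1 (1.48 ± 0.28), Col12a1 (1.34 ± 0.29) and Vcan (0.65 ± 0.21) up, beside Ccn2 (-0.75 ± 0.23) down and Postn (0.17 ± 0.23) and Acta2 (-0.21 ± 0.11) not called. The count of matrix genes was 17 down and 5 up of 30, the same within the list, at camera adjusted p = 0.00518 and adjusted p = 0.617 when estimated. Adipocyte genes fell, with Adrb3 (-2.98 ± 0.29) and Plin1 (-1.61 ± 0.23). Of 26 adipocyte genes 25 were down, the same within the list, at camera adjusted p = 3.25e-10 and adjusted p = 0.336 when estimated. Hamp2 (-7.74 ± 0.88), Akr1c14 (-4.88 ± 0.43), Usp50 (-4.45 ± 1.04) and Cilp (-4.43 ± 0.36), a cartilage matrix protein, were the other large decreases. In both plates 99.4% of the called genes had the same sign. Beside these falls, the median sum of skeletal muscle transcripts was 8740 CPM against 20600 in PBS. Of the calls 52.9% were increases (49.7% with deposited log2 values to 52.9% with hair score).

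At day 21 (7 and 8) matrix genes were raised in skin, with Col8a1 (2.84 ± 0.37), Col12a1 (1.94 ± 0.30), Postn (1.71 ± 0.24), Fn1 (1.27 ± 0.24), Col3a1 (0.99 ± 0.24) and Col1a1 (0.95 ± 0.27) up and Eln (-1.38 ± 0.26) and Col11a1 (-1.25 ± 0.51) down, next to Timp1 (2.84 ± 0.34), Spp1 (2.67 ± 0.55) and Ccn2 (0.86 ± 0.23) and the uncalled Acta2 (0.28 ± 0.12). Of 30 matrix genes 24 were up and 2 down, the same within the list, at camera adjusted p = 3.51e-09 and adjusted p = 0.252 when estimated. The cell cycle inhibitor Cdkn2a (4.10 ± 0.48) rose, and Cdkn1a (0.29 ± 0.09) rose slightly. Every interferon-induced gene rose, with Ifi44 (2.68 ± 0.34). Among interferon-induced genes 27 of 27 were up, the same within the list, at camera adjusted p = 1.44e-23 and adjusted p = 0.141 when estimated. Macrophage genes rose, with Fcgr1 (1.96 ± 0.30). Of 25 macrophage genes 22 were up and 1 down, 23 up and 1 down within the list, at camera adjusted p = 7.55e-15 and adjusted p = 0.141 when estimated. T and NK cell genes rose, with Cd4 (2.33 ± 0.27). Of 22 T and NK cell genes 17 were up, 18 up within the list, at camera adjusted p = 2.82e-10 and adjusted p = 0.141 when estimated. The largest increases were of the chemokine Cxcl5 (7.30 ± 1.00), above the PBS mean in 7 of 7 samples (adjusted p = 1.79e-08), and of Krt6b (7.07 ± 1.42), in 4 of 7, then BC100530 (6.12 ± 0.91), Myh7 (5.84 ± 1.46) and Akr1d1 (5.60 ± 0.96). Hair cycle and muscle content differed between the groups. Anagen hair genes, those of growing follicles, fell, led by keratin-associated genes such as Krtap6-3 (-6.71 ± 1.51) and Krtap16-3 (-6.24 ± 1.64). Of 30 anagen hair genes 25 were down, 27 down within the list, at camera adjusted p = 0.00537 and adjusted p = 0.741 when estimated. Hair transcripts summed to 59300, 55500 and 53400 CPM in PBS R1, R2 and R4, 60.6 to 7380 in the other 5 and 76.4 to 4450 after bleomycin, and Krtap16-3 was 0.28 with limma voom. Skeletal muscle genes rose, with Tcap (2.98 ± 0.59). Of 29 skeletal muscle genes 28 were up, 29 up within the list, at camera adjusted p = 6.17e-12 and adjusted p = 0.271 when estimated. With hair and muscle scores as terms of the model, chosen after seeing the data, these lists had camera adjusted p = 0.907 and adjusted p = 0.302, and 18 matrix genes rose. Called were 6521 genes, 3192 up and 3329 down (1185 and 640 at least 2-fold), with 97.4% of the same sign in both plates, against 3500 genes with only the 2 groups. Of the calls 48.9% were increases (46.2% with DESeq2 to 57.4% with the 2 groups alone).

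By day 28 (7 and 7) matrix genes were among those raised in skin. The largest increases were of Prss35 (5.37 ± 0.76), a secreted protease-like protein, Cthrc1 (4.67 ± 0.51), a product of activated fibroblasts, Jchain (4.33 ± 0.66), of plasma cells, Cxcl5 (4.29 ± 0.95) and the collagenase Mmp13 (4.25 ± 0.77), each above the PBS mean in 7 of 7 samples (adjusted p = 1.87e-11 for Cthrc1). Matrix genes rose, with Col8a1 (3.84 ± 0.40), Postn (2.83 ± 0.26), Col3a1 (1.95 ± 0.26), Fn1 (1.94 ± 0.25), Bgn (1.81 ± 0.19) and Col1a1 (1.81 ± 0.29). Among matrix genes 25 of 30 were up, the same within the list, at camera adjusted p = 6.97e-38 and adjusted p = 0.0101 when estimated. Genes of collagen processing rose, with Loxl2 (2.11 ± 0.21). Of 23 collagen processing genes 20 were up and 1 down, the same within the list, at camera adjusted p = 3.77e-25 and adjusted p = 0.0185 when estimated. Matrix proteases and inhibitors rose, with Adam12 (2.31 ± 0.33), Plat (1.43 ± 0.17) and Timp1 (2.94 ± 0.36). Of 26 matrix proteases and inhibitors 20 were up, the same within the list, at camera adjusted p = 9.95e-16 and adjusted p = 0.0185 when estimated. TGF-beta responsive genes rose, with Tgfb3 (1.25 ± 0.18) and Adam19 (1.04 ± 0.16), and Acta2 (0.33 ± 0.12) as well, with Ccn2 (0.57 ± 0.24) not called. Among TGF-beta responsive genes 10 of 28 were up, 12 up within the list, at camera adjusted p = 2.04e-06 and adjusted p = 0.0862 when estimated. Senescence genes rose, with Cdkn2a (5.24 ± 0.52) and Mmp3 (1.99 ± 0.33), and so did Spp1 (3.02 ± 0.58) and Cdkn1a (0.34 ± 0.09). Of 24 senescence genes 15 were up and 2 down, the same within the list, at camera adjusted p = 1.05e-05 and adjusted p = 0.0751 when estimated. Decreases were led by Slc26a7 (-3.19 ± 0.54), Marco (-3.06 ± 0.80), Myoc (-2.97 ± 0.51), Hamp2 (-2.81 ± 0.69) and the lectin Cd209g (-2.62 ± 0.35). Called were 3845 genes, 2015 up and 1830 down (576 and 192 at least 2-fold), with 98.2% of the same sign in both plates, against 6010 genes with limma voom and 5835 with the hair score. Median sums were 12300 CPM against 5420 in PBS for skeletal muscle and 8410 against 1450 for anagen hair. Of the calls 52.4% were increases (51.2% with limma voom to 59.3% with deposited log2 values).

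At day 42 (8 and 8) matrix genes were raised, with Col8a1 (3.30 ± 0.37), Col14a1 (1.59 ± 0.25), Mfap5 (1.51 ± 0.23), Col1a1 (1.53 ± 0.27), Col3a1 (1.37 ± 0.24), Fn1 (1.36 ± 0.23) and Postn (1.26 ± 0.23). The count of matrix genes was 22 up of 30, 26 up within the list, at camera adjusted p = 5.13e-29 and adjusted p = 0.0265 when estimated. Cthrc1 (3.59 ± 0.47) and Ccn3 (3.41 ± 0.38), a matricellular protein, rose most, in 8 of 8 samples (adjusted p = 3.36e-10 for Ccn3). TGF-beta responsive genes rose, with Nox4 (1.29 ± 0.28) and Eln (1.42 ± 0.25). The count of TGF-beta responsive genes was 10 up of 28, 14 up within the list, at camera adjusted p = 4.44e-08 and adjusted p = 0.0426 when estimated. Senescence genes rose, with Cdkn2a (5.17 ± 0.51) and Igfbp2 (1.35 ± 0.21), while Cdkn1a (0.17 ± 0.09) was not called. Among senescence genes 9 of 24 were up and 1 down, 9 up and 2 down within the list, at camera adjusted p = 1.74e-07 and adjusted p = 0.030 when estimated. Genes of Schwann cells, the glia of peripheral nerve, rose, with Sox10 (0.89 ± 0.15). Of 16 Schwann cell genes 10 were up, 14 up and 1 down within the list, at camera adjusted p = 1.37e-11 and adjusted p = 0.0146 when estimated. Endothelial genes rose, with Cdh5 (0.77 ± 0.13) and Emcn (0.60 ± 0.14). The count of endothelial genes was 10 up of 23, 13 up within the list, at camera adjusted p = 6.87e-09 and adjusted p = 0.151 when estimated. Timp1 (1.22 ± 0.33) and Spp1 (1.71 ± 0.54) rose and Acta2 (-0.36 ± 0.11) fell, with Ccl2 (0.62 ± 0.33), Ccn2 (0.34 ± 0.23) and Mki67 (-0.50 ± 0.25) not called. The muscle genes Myh3 (3.27 ± 1.09) and Tnnc1 (3.08 ± 0.76) were among the largest increases, and the largest decreases were of Inmt (-2.58 ± 0.82), Cd209g (-2.40 ± 0.32), Cd209f (-2.13 ± 0.27), the chemokine Cxcl13 (-2.20 ± 0.44) and Akr1cl (-2.10 ± 0.40). Called were 1622 genes, 834 up and 788 down (243 and 65 at least 2-fold), with 100% of the same sign in both plates. The count was 377 with only the 2 groups, 1036 without the plate term, 1019 with limma voom, 5183 with the hair score and 2788 with hair and muscle scores. Of the calls 51.4% were increases (45.9% with hair score to 76.4% with the 2 groups alone).

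**Figure D2:**
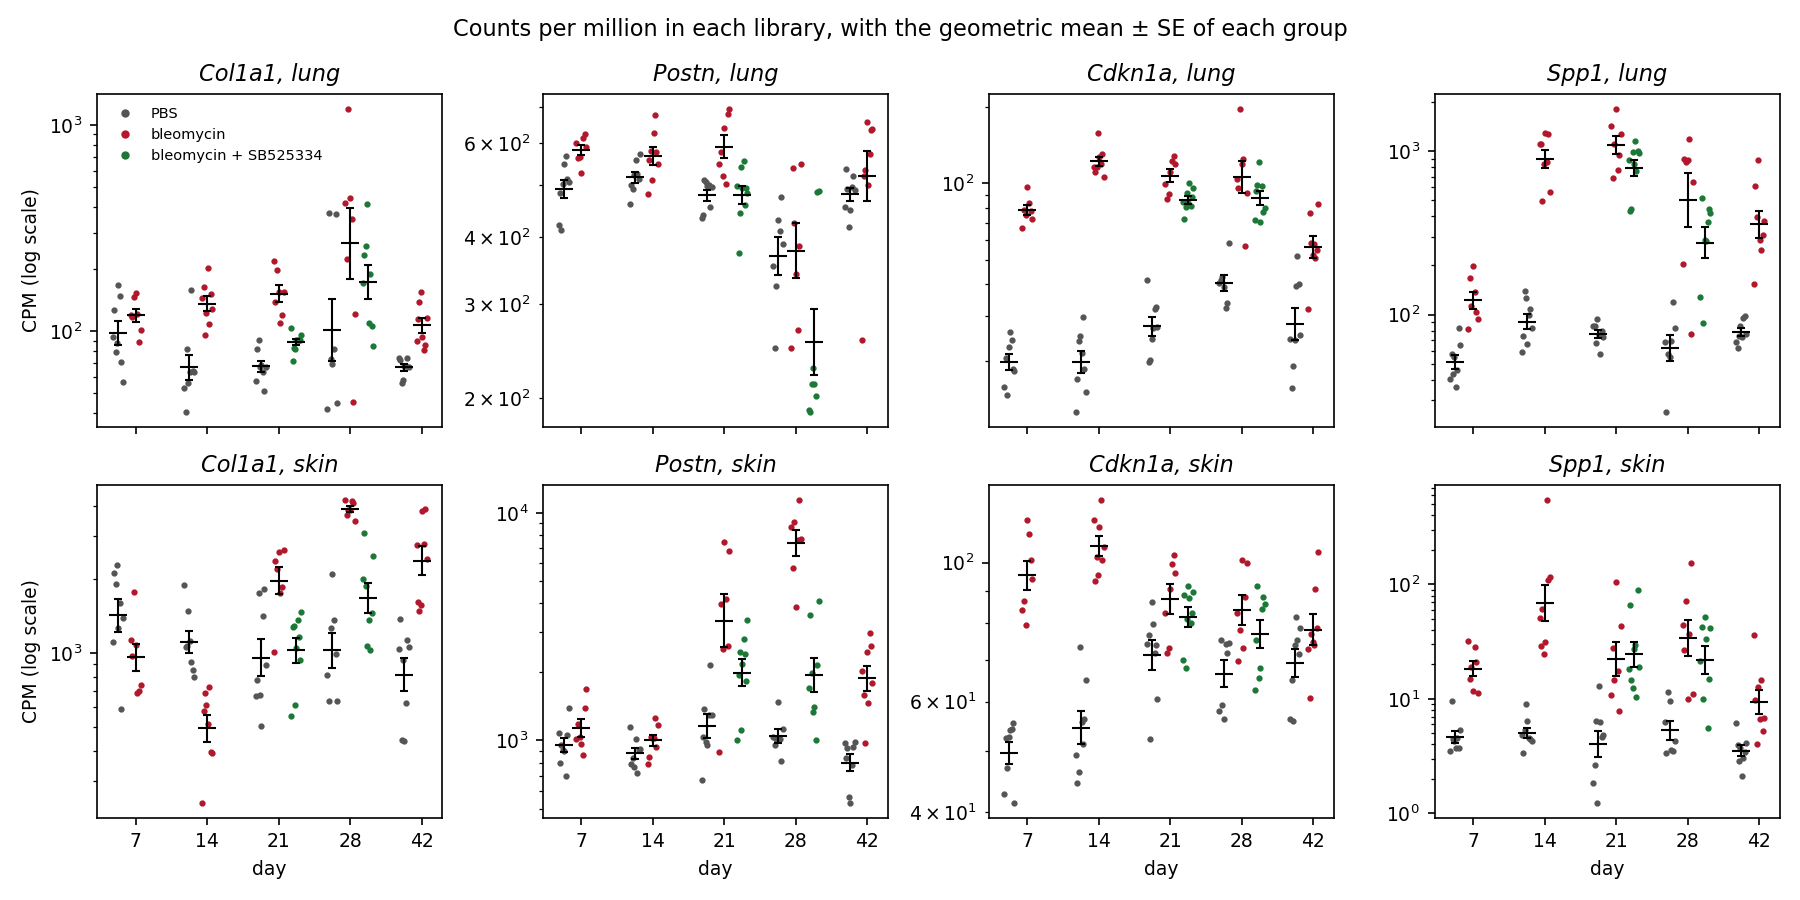
CPM (log axis) of Col1a1, Postn, Cdkn1a and Spp1 in each library of lung and skin by day, with PBS in grey, bleomycin in red and bleomycin with SB525334 in green, and bars for the geometric mean ± SE of the log2 values. Postn rose in skin at day 28 by 2.833 log2 units and Cdkn1a in lung at day 14 by 2.596.

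**Figure D3:**
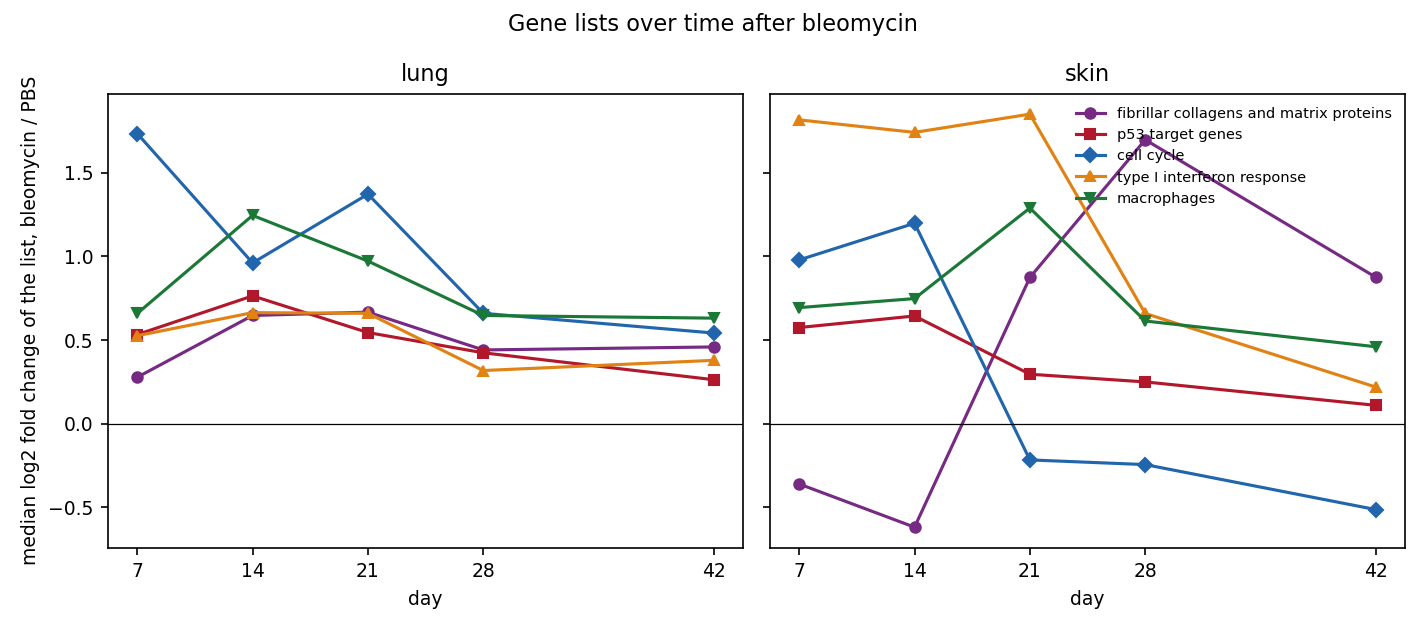
Median log2 fold change of 5 gene lists (y axis, bleomycin over PBS) against day for lung and skin. The matrix median in skin went from -0.618 at day 14 to 1.697 at day 28.

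**Figure D4:**
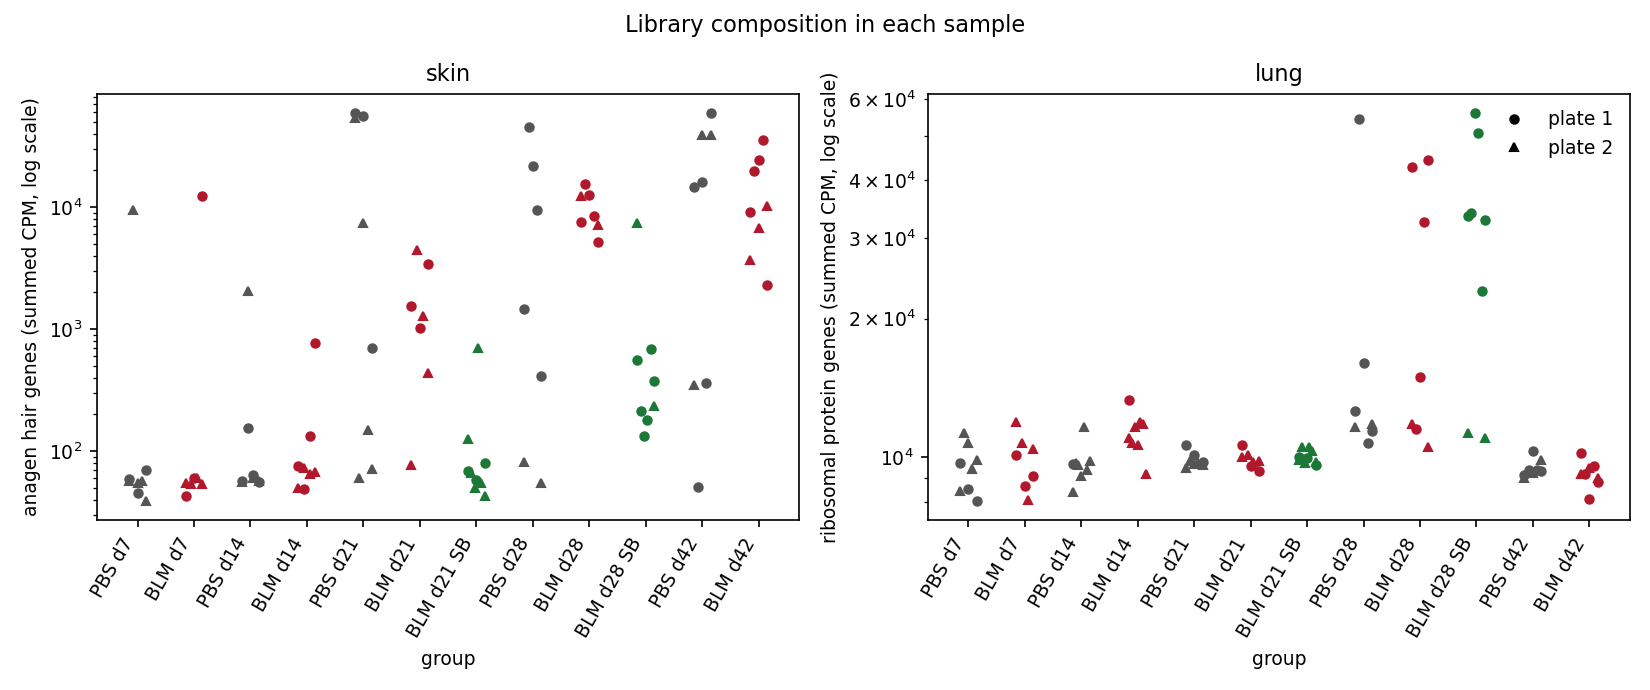
Summed CPM (y axis, log scale) of anagen hair follicle genes in skin and of cytosolic ribosomal protein genes in lung in each library by group, with plate 1 as circles and plate 2 as triangles. Hair genes ranged from 39.2 to 59300 CPM and ribosomal protein genes from 8030 to 56100 CPM.

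With SB525334 in day 21 skin (9 against 7) epidermal genes rose and matrix genes fell. The suprabasal keratin Krt2 (4.23 ± 0.49) rose from 0.879 ± 0.703 to 17.3 ± 15.2 CPM (mean ± SD), above the vehicle mean in 9 of 9 samples (adjusted p = 4.68e-09). The cornified envelope genes Sprr2d (2.70 ± 0.72) and Lce3e (1.97 ± 0.59) and the inhibitors Serpinb3a (2.37 ± 0.54) and Stfa2 (2.32 ± 0.73) followed, Stfa2 in 5 of 9. Interfollicular epidermis rose as a list, with Dsg1b (0.95 ± 0.17) and Krt5 (0.54 ± 0.11). Of 25 epidermis genes 14 were up, 20 up and 1 down within the list, at camera adjusted p = 5.13e-15 and adjusted p = 0.114 when estimated. Matrix genes fell, with Col14a1 (-1.16 ± 0.25), Postn (-0.93 ± 0.23), Col1a1 (-0.93 ± 0.27), Col3a1 (-0.72 ± 0.23) and Bgn (-0.69 ± 0.17). Of 30 matrix genes 14 were down, 21 down within the list, at camera adjusted p = 3.94e-09 and adjusted p = 0.522 when estimated. Fibroblast markers fell, with Mfap4 (-1.67 ± 0.30), Fap (-0.94 ± 0.16) and Cd34 (-0.89 ± 0.19). Of 20 fibroblast markers 12 were down, 14 down within the list, at camera adjusted p = 3.94e-09 and adjusted p = 0.347 when estimated. Other anchors were not called, with Fn1 (-0.37 ± 0.23), Ccn2 (-0.32 ± 0.23), Timp1 (-0.06 ± 0.31), Cdkn1a (-0.11 ± 0.09) and Spp1 (0.01 ± 0.50). Hair genes led the decreases, Krtap5-2 (-4.92 ± 1.72), Krt35 (-4.33 ± 1.51), Foxe1 (-3.82 ± 1.26), Krt28 (-3.53 ± 1.21) and Mycn (-2.58 ± 0.73), as part of a lower anagen list. Among anagen hair genes 3 of 30 were down, 27 down within the list, at camera adjusted p = 3.12e-08 and adjusted p = 0.701 when estimated. Called were 1872 genes, 919 up and 953 down (73 and 134 at least 2-fold), with 99.4% of the same sign in both plates. Voom called 3441, the hair score 4638 and hair and muscle scores 3864 (18 matrix genes down). Of the calls 49.1% were increases (45.5% with hair score to 56.5% with no filter).

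At day 28 (8 against 7) SB525334 lowered matrix genes in skin, with Postn (-1.84 ± 0.24), Col14a1 (-1.47 ± 0.26), Col5a2 (-1.30 ± 0.20), Col3a1 (-1.18 ± 0.24), Col1a1 (-1.12 ± 0.28) and Bgn (-1.10 ± 0.18). Among matrix genes 25 of 30 were down, 26 down within the list, at camera adjusted p = 6.26e-20 and adjusted p = 0.27 when estimated. Beside this, epidermis transcripts summed to 25900 to 35700 CPM against 16000 to 23900 on vehicle. Genes of collagen processing fell, with Serpinh1 (-0.93 ± 0.17), a collagen chaperone. Among collagen processing genes 14 of 23 were down, 18 down and 1 up within the list, at camera adjusted p = 6.2e-09 and adjusted p = 0.536 when estimated. TGF-beta responsive genes fell, with Cilp (-2.20 ± 0.33), Cthrc1 (-2.08 ± 0.43), Nox4 (-1.57 ± 0.29) and Eln (-1.26 ± 0.26), and so did Acta2 (-0.53 ± 0.12) and the fibroblast gene Mfap4 (-2.50 ± 0.32). Of 28 TGF-beta responsive genes 11 were down and 2 up, 13 down and 2 up within the list, at camera adjusted p = 1.25e-04 and adjusted p = 0.536 when estimated. Values of Fn1 (-0.47 ± 0.23), Ccn2 (-0.42 ± 0.23), Timp1 (0.14 ± 0.32), Cdkn1a (-0.12 ± 0.09) and Spp1 (-0.82 ± 0.51) were not called. Krt2 (3.95 ± 0.49) and Marco (3.58 ± 0.79) rose most, each above the vehicle mean in 8 of 8 samples (adjusted p = 3.25e-09 for Krt2), then Saa3 (2.97 ± 0.76) in 6 of 8, Cxcl5 (2.63 ± 0.71) in 5 of 8, and Mup2 (2.23 ± 0.50). Sebaceous gland genes rose, with Elovl3 (0.97 ± 0.21). Of 18 sebaceous genes 13 were up and 1 down, 14 up and 1 down within the list, at camera adjusted p = 1.24e-06 and adjusted p = 0.536 when estimated. Antigen presentation genes rose, with Tap1 (0.52 ± 0.15). Among antigen presentation genes 12 of 20 were up, 15 up within the list, at camera adjusted p = 4.24e-06 and adjusted p = 0.566 when estimated. Interferon-induced genes rose, with Oas3 (1.23 ± 0.39). The count of interferon-induced genes was 10 up of 27, 14 up within the list, at camera adjusted p = 2.72e-05 and adjusted p = 0.591 when estimated. With hair and muscle scores as terms, 0 and 0 of these rose (camera adjusted p = 0.154 and adjusted p = 0.247), whereas 28 matrix genes fell. Keratin-associated hair genes led the decreases, with Krtap6-3 (-4.87 ± 1.45), Krtap19-4 (-4.77 ± 1.48) and Krtap16-3 (-4.43 ± 1.5). Called were 3783 genes, 1938 up and 1845 down (166 and 392 at least 2-fold), with 99.7% of the same sign in both plates, against 6622 genes with limma voom. Of the calls 51.2% were increases (39.2% with hair and muscle scores to 51.7% with replicate block).

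Genes called at day 14 of bleomycin were followed under SB525334 with camera, unadjusted. In day 21 skin the 4983 genes raised by bleomycin shifted up (p = 2.3e-19, and p = 0.0053 with estimated correlation) and the 4445 lowered ones down (p = 1.39e-21, and p = 0.012 with estimated correlation), so only 32.2% and 19.9% moved against bleomycin. At day 28, 46.7% of the raised and 47.8% of the lowered day 14 genes moved against the day 14 effect, with medians of 0.017 and -0.015. Both sets shifted only slightly with the day 14 effect (p = 0.0112, and p = 0.423 with estimated correlation for raised genes, p = 0.0146, and p = 0.512 with estimated correlation for lowered ones). In day 21 lung the sets shifted against the day 14 effect of lung, with raised genes down (p = 0.00257, and p = 0.386 with estimated correlation) and lowered genes up (p = 7.9e-04, and p = 0.378 with estimated correlation), 57.4% and 66.3% moving oppositely. In day 28 lung raised genes tested towards up although their median, -0.009, and mean, -0.03, were negative (p = 0.364, and p = 0.794 with estimated correlation), and lowered genes shifted down (p = 0.0172, and p = 0.532 with estimated correlation).

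Between day 14 and day 42 the bleomycin effect on the lung changed for 2394 genes, 1666 towards larger and 728 towards smaller log2 fold changes. The share of larger effects, 69.6%, went to 55.8% without libraries with other tissues and 48.2% of 4725 genes without all doubted ones. The DNA damage response receded, with Mdm2 (-0.63 ± 0.07), Ccng1 (-1.31 ± 0.15) and Cdkn1a (-1.62 ± 0.24). Among p53 targets 13 of 32 were smaller, 16 smaller within the list, at camera adjusted p = 4.21e-14 and adjusted p = 1.73e-04 when estimated. So did transitional epithelium, with smaller effects also for the injury gene Ankrd1 (-1.89 ± 0.23) and Ccl2 (-1.81 ± 0.62). The count of transitional epithelium genes was 9 smaller and 1 larger of 20, 10 smaller and 1 larger within the list, at camera adjusted p = 4.98e-11 and adjusted p = 0.0202 when estimated. B cell genes gained, together with C1qtnf3 (3.35 ± 0.43), an adipokine-like fibroblast product, Fbxo32 (1.09 ± 0.14) and Rnf43 (0.76 ± 0.10). The count of B cell genes was 14 larger of 15, 15 larger within the list, at camera adjusted p = 3.5e-07 and adjusted p = 0.355 when estimated. Differences of Col1a1 (-0.25 ± 0.46), Fn1 (-0.54 ± 0.40) and Spp1 (-0.94 ± 0.42) were not called.
The F test over all 5 days called 4149 genes, led by Fbxo32, Mdm2, Trem1, Ankrd1 and Il33 (adjusted p = 2.75e-11 for Mdm2).
Among PBS lungs 3392 genes differed between days, led by the clock genes Arntl, Dbp, Bhlhe41, Per3 and Nr1d2 and by Tspan4 (adjusted p = 1.2e-28 for Arntl). Without doubted libraries the F test called 7414 and the PBS test 5888.

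In skin the same difference was called for 8055 genes, 3643 larger and 4412 smaller at day 42. Matrix genes gained, with Fn1 (2.76 ± 0.33), Col1a1 (2.67 ± 0.38), Col3a1 (2.52 ± 0.33), Postn (1.08 ± 0.33) and Ccn2 (1.08 ± 0.32). The count of matrix genes was 23 larger and 2 smaller of 30, 25 larger and 2 smaller within the list, at camera adjusted p = 2.25e-12 and adjusted p = 0.36 when estimated. So did fibroblast markers, with the matrix-associated gene Fndc1 (3.96 ± 0.31) and Fam198a (3.45 ± 0.29) ahead of all single genes. Among fibroblast markers 17 of 20 were larger, the same within the list, at camera adjusted p = 1.43e-12 and adjusted p = 0.0881 when estimated. The effect on p53 targets was smaller, with Cdkn1a (-0.78 ± 0.12). The count of p53 targets was 20 smaller and 1 larger of 32, the same within the list, at camera adjusted p = 3.97e-06 and adjusted p = 0.0271 when estimated. That on interferon-induced genes was smaller. Of 27 interferon-induced genes 25 were smaller, the same within the list, at camera adjusted p = 6.48e-09 and adjusted p = 0.392 when estimated. The effect on the cell cycle was smaller, with Mki67 (-1.64 ± 0.36), as were those on Spp1 (-2.69 ± 0.75), Timp1 (-1.46 ± 0.46) and Ccl2 (-1.22 ± 0.47). Among cell cycle genes 34 of 35 were smaller, the same within the list, at camera adjusted p = 5.48e-12 and adjusted p = 0.392 when estimated.
Over all 5 days the F test called 9815 genes, led by Fndc1, Rbms3, Eml1, Fam171b and Mfap5 (adjusted p = 1.25e-20 for Fndc1).
PBS skin differed between days in 8739 genes, led by the clock genes Per3, Tef, Per2 and Dbp and the immediate early genes Fos and Egr1 (adjusted p = 1.27e-22 for Per3). The count of genes differing between PBS days was 2772 with the hair score and 2435 with hair and muscle scores. A random split called more genes than the real one (5683 against 5551 with limma-trend).

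The bleomycin effects of the 2 tissues differed on every day. Positive differences denote a larger log2 fold change in skin. At day 7 2754 genes differed, 1430 higher and 1324 lower in skin. Interferon-induced genes responded more in skin (23 higher of 27, 25 higher within the list) and matrix genes less (14 lower of 30, 1 higher and 18 lower within the list), with Fn1 (-1.96 ± 0.38), Col3a1 (-1.41 ± 0.35) and Cdkn1a (-1.09 ± 0.20) lower, and Traf1 (1.63 ± 0.17) and Ly6c2 (3.52 ± 0.43) higher.
At day 14 5358 genes differed (2583 higher and 2775 lower), with matrix genes lower in skin (2 higher and 21 lower of 30, 3 higher and 21 lower within the list), Fn1 (-3.45 ± 0.38), Col3a1 (-2.25 ± 0.34), Col1a1 (-2.12 ± 0.43), Ccn2 (-1.57 ± 0.27) and Cdkn1a (-1.69 ± 0.19) among the named ones, next to Cd34 (-3.0 ± 0.21) and Bmp4 (-2.48 ± 0.19).
The 4986 genes of day 21 (2233 and 2753) included more positive effects in skin for T and NK cells (20 higher of 22, the same within the list), Postn (1.34 ± 0.27) and Ifi213 (3.64 ± 0.38), and lower ones for the cell cycle (31 lower of 35, 33 lower within the list), p53 targets (4 higher and 17 lower of 32, the same within the list), Cdkn1a (-1.71 ± 0.20), Mki67 (-1.97 ± 0.41), Ctsd (-2.15 ± 0.17) and Psrc1 (-3.91 ± 0.36).
At day 28, with 4314 genes (1758 and 2556), matrix genes responded more in skin (23 higher of 30, 23 higher and 1 lower within the list), with Postn (2.74 ± 0.28), Col3a1 (1.58 ± 0.37) and Timp1 (2.01 ± 0.62), while Cdkn1a (-1.18 ± 0.20) was lower and Col1a1 (0.46 ± 0.46) not called. Without doubted libraries 2719 were called, and a random split called 2089 against 1384 with limma-trend.
At day 42 2008 genes differed (826 and 1182), with endothelial genes higher in skin (16 higher of 23, 18 higher within the list), Ccn3 (3.30 ± 0.38), Col8a1 (2.96 ± 0.39) and Postn (1.11 ± 0.26) among the higher genes and Cdkn1a (-0.79 ± 0.19) and Nrcam (-2.27 ± 0.27) among the lower. Higher ones made up 41.1%, and 50.6% without doubted libraries. The lowest differences at days 28 and 42, such as Krt4 and Mup3, came from doubted lung libraries.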

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

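Each library was set against the others of its group on 11 measures, and in 46 of 264 sets 1 library stood apart by Dixon's gap test. Chance flags about 1 in 20 groups. Replicate numbers (R) are those of the labels. Total counts in M were 4.79 in PBS day 28 lung R2, 32.73 in PBS day 14 skin R5 and 43.07 in PBS day 21 skin R2. All further values are summed CPM of a list. PBS day 28 lung R2 also stood apart for ribosomal proteins (54300), histones (4210), mitochondrial genes (24500), red cells (48700) and epidermis (161). PBS day 14 lung R6 did so for hair (8560), epidermis (2340), type 2 pneumocytes (17300), red cells (10500) and ribosomal proteins (11600). Bleomycin day 28 lung R2 did so for skeletal muscle (16100), cardiac muscle (9300) and epidermis (2130). Bleomycin day 42 lung R1 did for mitochondrial genes (34800), type 2 pneumocytes (10700) and brown fat (1110), though its marker Ucp1 was 0.

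Hair values in skin stood apart at 12300 in bleomycin day 7 R3, 9570 in PBS day 7 R5, 7380 in SB525334 day 28 R7, 2040 in PBS day 14 R6, 771 in bleomycin day 14 R4 and 704 in SB525334 day 21 R7. In lung they did at 411 in PBS day 21 R3, 80 in bleomycin day 14 R8, 65.5 in day 7 R7 and 55.9 in day 42 R3. Epidermis values were 19900 in PBS day 7 skin R8, 199 in SB525334 day 21 lung R3, 116 in bleomycin day 14 lung R7 and 84.4 in day 42 lung R3. Red cell values were 51200 in SB525334 day 21 lung R6, 12200 in its vehicle R3, 5520 in bleomycin day 42 lung R5, 1080 in bleomycin day 28 skin R4 and 829 in day 21 skin R3, where the pneumocyte value was 1380. Mitochondrial values were 17100 in bleomycin day 14 skin R5, with skeletal muscle at 13500, and 17000 in day 28 skin R7. The last values were 1250 for skeletal muscle in SB525334 day 21 lung R2, 155 for brown fat in PBS day 42 lung R6, and 548 and 1250 for cardiac muscle in bleomycin day 21 lung R5 and day 42 lung R6.

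Tests of a difference between days or tissues called 2394 genes for day 42 minus day 14 and 4149 over all days in lung, 8055 and 9815 in skin, and 2754, 5358, 4986, 4314 and 2008 for skin minus lung on days 7, 14, 21, 28 and 42.

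In day 28 lung, ribosomal protein genes summed to more than 20000 CPM in 10 libraries, all of plate 1 and 6 of them on SB525334. The test within plate 2 was chosen only after the result was seen. An excess of short transcripts in these libraries was tested through exon length, and the SB525334 fold changes of genes outside these lists fell with length (Spearman rho = -0.401, and -0.0401 without those libraries), the value set beforehand for such an excess. Against a response to SB525334 stood plate 2, where the ribosomal protein median was -0.0597 against 0.462 in plate 1. Plate 2 held only 2 lungs per group, and its histone median, 0.443 against 0.344, leaves a response of histone genes open. What set these plate 1 libraries apart stays open.

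Hair follicle transcripts in skin varied widely between libraries. With the hair score as a term, 3199 genes were called for SB525334 at day 28 against 3783 without it. As the term also brought new calls, the total does not decide, and 1954 genes were called in both. The matrix median was -1 with hair and muscle scores as terms and -1.03 without. Hair transcripts, however, nearly separated the groups, at 5230 to 15500 CPM on vehicle and 132 to 683 with SB525334, except 7380 in R7. The terms were fitted on differences within all 12 groups, so these values cannot tell hair cycle from treatment. The inhibitor could itself alter the hair cycle, and this was not tested.

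Clock genes differed with SB525334 in day 21 lung. If time of sampling were the source, lung and skin taken at the same time should move alike, and they did (Spearman rho = 0.903, 16 of 18 genes with the same sign). A lasting response to SB525334 should recur at day 28, and it did (rho = 0.93, 13 of 18), so both explanations stay open.

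Within each comparison the libraries were regrouped at random into groups of the same sizes, within day for the tests between days and within tissue for skin minus lung, and limma-trend counts of 100 splits, the real one included, were compared. Values are the real count against the highest other, with the number of splits reaching the real count in parentheses. In lung, bleomycin gave 6820 against 3811 (1), 8504 against 4954 (1), 8707 against 4971 (1), 121 against 530 (3) and 3355 against 741 (1) on the 5 days, SB525334 887 against 92 (1) and 0 against 1 (100), day 42 minus day 14 3591 against 2 (1), the F test 3132 against 4670 (4) and PBS days 5674 against 51 (1). In skin the values were 7491 against 0 (1), 9986 against 7433 (1), 3499 against 1621 (1), 2993 against 557 (1) and 407 against 3350 (2), then 2419 against 45 (1) and 5445 against 2144 (1), 7769 against 4098 (1), 9063 against 4529 (1) and 5551 against 5683 (2). Skin minus lung gave 3590 against 970 (1), 6765 against 3713 (1), 4861 against 789 (1), 1384 against 2089 (2) and 968 against 967 (1). Fewer than 5 of 100 splits reached the real count for all except SB525334 in day 28 lung. There limma-trend called none in the real split, so the test says nothing. Among the rest another split called more than the real one for day 28 and the F test of lung. The same held for day 42 and PBS days of skin, and skin minus lung at day 28. Splits can keep part of the real grouping, so the source is open. The counts are of limma-trend on the compared groups, not of the edgeR fits reported above. They were not adjusted over the results, so they do not exclude chance in the reported calls.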

How the results depend on the processing

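The alternatives were chosen before the data were examined, except those that left out lung libraries or added hair and muscle scores, chosen after seeing the data. The doubted lung libraries were 5 with transcripts of other tissues, with epidermis genes above 1000 CPM in sum or Alb above 100 CPM, and 10 with ribosomal protein genes above 20000 CPM. Of 307 counts and list results under alternatives, 231 kept their direction and side of the threshold or lay within 1.5 times the reported count, 62 moved, 12 no longer passed and 2 changed direction. Counts of called genes moved under none of RLE size factors, no filter, plate sections, the deposited log2 values and, in lung, leaving out 3 libraries with over 13% of counts in 10 genes. For the shifts given here the cause was not tested.

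In fits of the 2 groups alone the counts were 8695, 112 and 890 for lung bleomycin on days 21 and 28 and SB525334 on day 21, and 3500 and 377 for skin bleomycin on days 21 and 42. For SB525334 in day 28 lung this edgeR fit called 0 genes, with 1388 at an unadjusted p under 0.05, where DESeq2 with all groups called 1543 and voom 43. With voom, lung gave 7928, 9231 and 5531 for bleomycin on days 7, 21 and 42 and 1316 for SB525334 on day 21, and skin 6010 and 1019 for bleomycin on days 28 and 42 and 3441 and 6622 for SB525334 on days 21 and 28. DESeq2 gave 127 for SB525334 in day 21 lung, and skin bleomycin at day 42 gave 1036 with no plate term.

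Without the libraries with other tissues, SB525334 gave 150 and 683 in lung on days 21 and 28. Without those high in ribosomal protein it gave 140 and 66, with 3693 for bleomycin at day 28, 4380 for day 42 minus day 14, 7162 for the F test and 5329 for PBS days. Without both kinds the values in this order were 337, 142, 3471, 4725, 7414 and 5888, and 2719 for skin minus lung at day 28. With the hair score skin bleomycin gave 5835 and 5183 on days 28 and 42, SB525334 4638 at day 21 and PBS days 2772. With hair and muscle scores the values were 2788 for bleomycin at day 42, 3864 for SB525334 at day 21 and 2435 for PBS days.

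Gene lists passing camera fell most with an estimated correlation, to 1, 4, 4, 1 and 2 for lung bleomycin on the 5 days, 1 and 1 for SB525334 and 2 for day 42 minus day 14, and in skin to 1, 1, 0, 3 and 4, 0 and 0 and 1. The preset correlation gave 18, 18, 21, 24, 28, 16, 20 and 23 in lung and 22, 26, 26, 22, 27, 16, 20 and 27 in skin. With fry 2, 10 and 13 lists passed for SB525334 on days 21 and 28 and day 42 minus day 14 in lung, and 17 for skin at day 42. The skin SB525334 lists at day 28 came to 11 with hair and muscle scores.

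For the day 14 signature under SB525334, unadjusted p-values with the estimated correlation and with fry were 0.386 and 0.611 for raised and 0.378 and 0.34 for lowered genes in day 21 lung, 0.532 and 0.298 for lowered genes in day 28 lung, and 0.423, 0.28, 0.512 and 0.251 for raised and lowered genes in day 28 skin. Other values here are of camera at the preset correlation. Limited to 2-fold changes they were 0.107 and 0.092 in day 21 lung. In day 28 lung the shift changed direction without passing, with 0.766 for raised and 0.0799 for lowered genes at 2-fold, and 0.325 and 0.563 without both kinds of library. The day 7 signature gave 3.32e-05 for lowered genes there, but 0.265 with the estimated correlation and 0.0743 with fry.

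Of 4833 values of named genes under alternatives, 4538 kept direction and side of the threshold, 48 newly passed, 219 no longer passed, 14 moved and 14 changed sign. Without both kinds of library Postn under SB525334 in day 28 lung was 0.062. Rpl10-ps3 there was -0.071 without high ribosomal protein and -0.257 without both kinds. Without other-tissue libraries and without both kinds, Krtap11-1 was 0.301 and 0.277 in day 14 lung and Tgm3 was -1.388 and -1.724 in day 28 lung. With voom, Krtap16-3 was 0.096 in day 14 lung and 0.275 in day 21 skin, and Col6a5 was 0.24 in day 28 lung. Krtap16-3 in skin was 0.622 and 0.674 with the hair score and with both scores for bleomycin at day 21, and 0.462 and 0.392 for SB525334 at day 28.

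With the replicate number as a replicate block the counts were 4709, 7003, 5351, 5673 and 2820 for lung bleomycin, 41 and 1039 for SB525334, and 2037, 3474 and 2791 for day 42 minus day 14, the F test and PBS days, and in skin 7136, 9340, 6354, 3699 and 1424, 1820 and 3552, and 7921, 9552 and 8475. None moved by over 1.5 times. The labels give no animal or litter shared by a number. The numbers follow plate and well order in 24 of 24 groups, and same-numbered samples mostly shared a plate. From 0 to 4 of 7 or 8 same-numbered pairs per comparison correlated above 0.1, and 0 to 2 samples correlated best with their own number, so the numbers were not taken as pairs.

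Whether depth limited recovery of simulated 1.5-fold changes in day 7 lung, 76 of 100, was not tested.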

Other observations

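The transcripts of other tissues in single lung libraries were of more than 1 kind. Alb, a liver transcript, reached 13600 CPM against a median of 1.12, and Krt4, a keratin of stratified squamous epithelium, 4910 CPM against 0.182. The surfactant transcript Sftpc reached 308 CPM in 1 skin library, where the median was 4.06 and that of lung 8130. Every library had the pneumocyte or epidermis level of its labelled tissue. Pneumocyte genes summed to at least 10700 CPM in lung, and epidermis genes to at least 11500 CPM in skin.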
